A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

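RNA of the haploid laboratory yeast strain BY4741 was measured on Affymetrix arrays, with 3 arrays labelled wild type and 3 labelled as carrying a deletion of YPR045C. Per the labels' protocols, the cells grew exponentially in rich medium (YPD), total RNA was extracted with a column kit, and biotin-labelled cRNA was hybridised. The labels give the arrays of each group the numbers 1 to 3. They do not say whether the 3 RNAs of a group came from separate cultures, so p-values measure the spread between these arrays, which may be partly technical.

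The authors deposited 1 intensity per probe set and array, on a linear scale. How the probe signals were summarized, corrected for background and scaled is not given in the sources used here. The table held 10928 probe sets and 30 missing values, in 28 probe sets, 12 of which stood for genes tested here. Summed intensity ranged from 17790600 to 18431400 per array. The log2 medians over all probe sets differed by up to 0.26 between arrays.

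Probe sets were named through the platform's gene table, with symbols updated through the gene identifier in 12 cases against the R64 gene table. A single S. cerevisiae gene was given for 5498 probe sets, which stood for 5449 genes. A further 1746 probe sets belonged to fission yeast (S. pombe) genes, 1 listed several genes, 213 were control or reporter probe sets and 3470 were unnamed. For the 47 genes with more than 1 probe set, the one with the highest mean over the 6 arrays was used. No genome sequence was used here, so chromosome and gene order come from the R64 table and coordinates are not printed.

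Because the log2 medians differed by more than 0.1, the rule set before the data were examined called for quantile normalization of all probe sets. Values were then taken as log2(normalized intensity + 16). Fold changes are on that scale, which understates changes of dim genes. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with the group as the only term. The threshold was an adjusted p of 0.05 by the Benjamini-Hochberg method over the 5449 genes, and genes that also differed at least 2-fold were counted apart. Intervals are at 95%. As a measure of background, the 95th percentile of the means of the S. pombe probe sets was used, which lay at 6.48 on the log2 scale. Where the dimmer group lay below it, a fold is given as a bound against that limit.

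In all, 50 gene lists were written from general knowledge before the data were examined. One of them held the neighbours of THP3 and was not tested as a list, and 3 had fewer than 5 measured members. The other 46 were tested with camera of limma at its preset inter-gene correlation of 0.01, and again with the correlation estimated from the data. The same test was run on 3 classes of intron-containing and ribosomal protein genes and on the 16 chromosomes. Introns were taken from lists written by hand, since the gene table used here gives no exons. A further list, of ribosomal protein genes without an intron, was written after the files were seen but before any test. Medians per array were compared with an exact two-sided permutation test, which cannot give a p under 0.1 with 3 against 3 arrays. Gene length was taken from the R64 table. It includes introns, so it exceeds the coding length of intron-containing genes.

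The genes named are THP3 and the nearest protein-coding genes on either side, the 10 largest rises and the 10 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each described list with the smallest p. This rule was also set before the data were examined. Genes whose values are given outside it, among them PHO86, VTC4, RPL43B and EAF5, were chosen after their values were seen.

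The fit was tested on simulated data for this comparison, drawn for the 5449 genes with the measured means. The spreads were those estimated by the fit itself, so it was tested only under its own model. Of genes changed by 0.5 on the log2 scale 93% were called, and of genes changed by 1 it was 99%. Of all calls, 5.42% fell on unchanged genes. A simulated list shifted by 0.3 passed, and 0 of the unshifted lists did. Genes were drawn independently of each other, so these lists do not test the preset inter-gene correlation.

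The alternatives were the values as deposited, median centring, other pseudocounts, a filter on dim genes, another spread model, all probe sets, the array number as a block, an unmoderated test, and each array left out. After the data were seen, 4 more were added: without chromosome X genes, without both arrays numbered 3, with those arrays as a batch, and quantile normalization over S. cerevisiae probe sets alone. The number of arrays limits the precision of every value.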

Results

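The series compared genome-wide mRNA levels of 3 arrays labelled wild type with 3 arrays labelled as a deletion of YPR045C, all in the BY4741 background. YPR045C encodes Thp3, a protein linked to transcription elongation and mRNA processing. Array values correlated at r = 0.9957 to 0.9965 within the group labelled wild type and at 0.9949 to 0.9970 within the group labelled deletion, across 5437 genes. Between the groups r was 0.981 to 0.985. The first principal component held 72.3% of the variance and separated the labelled groups. The second held 13.2% and set both arrays numbered 3 apart from the other 4. The probe set of 5.8S rRNA, looked at after the data were seen, stood at 8.85 and 8.39 in those and between 12.87 and 13.46 in the others. Of 7 rRNA probe sets 6 were higher in the arrays labelled deletion and 1 lower, and limma called 0 (lowest adjusted p = 0.36; 0 at an unadjusted p under 0.05). The largest of these differences was that of an 18S probe set, with 8.30, 10.76 and 8.32 in the arrays labelled wild type and 13.13, 12.39 and 8.81 in those labelled deletion.

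The targeted gene was measured first, as a check of the labels. THP3 (YPR045C, chromosome XVI) was not lower in the arrays labelled deletion. Its deposited intensity was 732.51, 677.63 and 462.77 in the arrays labelled wild type and 949.98, 894.03 and 528.86 in those labelled deletion. The means were 624 ± 143 and 791 ± 229 (SD, n = 3 each), and the log2 difference was 0.33 ± 0.25 (SE; limma adjusted p = 0.39; exact permutation p = 0.4). The signal stood 6.99-fold over the background limit in arrays labelled wild type and 8.77-fold over it in arrays labelled deletion. With the arrays numbered 3 as a batch, THP3 was higher in the arrays labelled deletion (adjusted p = 0.015), and with both left out the adjusted p was 0.020; over all alternatives it ranged from 0.015 to 0.73. The measured level thus goes against the label. A level above the limit does not by itself show an intact gene, however. LEU2, which is deleted in BY4741, stood at 8.79 in the arrays labelled wild type and 8.52 in those labelled deletion. THP3 stood at 9.29 and 9.62. URA3 and MET17, also deleted in BY4741, lay below the limit in both groups. No table used here places the probes within the gene or gives the deleted part, and a probe set outside that part would check nothing. Groups are therefore named by their labels throughout, and each direction rests on them.

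Among the nearest genes of THP3, RPL43A (YPR043W), which encodes a protein of the large ribosomal subunit, was 4.99-fold higher in the arrays labelled deletion (log2 difference 2.32 ± 0.07, adjusted p = 1.57e-05). PUF2, MCM16 and MSF1 differed by 0.20, 0.23 and 0.20 and were not called. With the arrays numbered 3 as a batch, PUF2 and MCM16 were called higher (adjusted p = 0.030 and 0.029), and with median centring MSF1 was (adjusted p = 0.037). One probe set outside the gene table showed the reverse. The reporter probe set RPTR-Sc-AJ002682-1_s_at stood at 14.11 ± 0.03 (SD, n = 3) in the arrays labelled wild type and at 5.41 ± 0.09 in those labelled deletion, below the background limit of 6.48. It was at least 197-fold higher in the arrays labelled wild type (limma adjusted p = 1.70e-08).

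**Figure D1:**
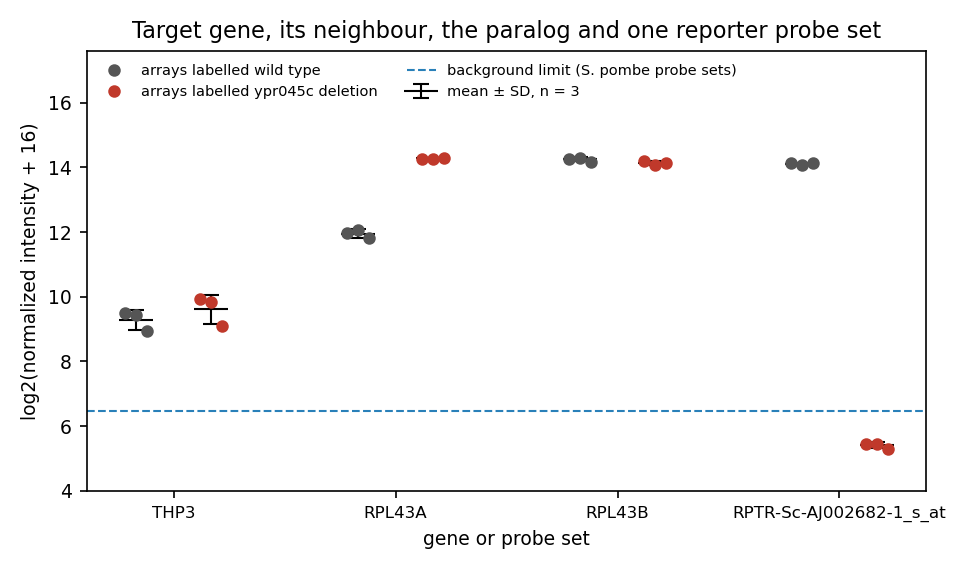
Log2(normalized intensity + 16) of THP3, RPL43A, RPL43B and 1 reporter probe set in the 6 arrays (points), with mean ± SD of the 3 arrays of each labelled group (black) and the background limit of 6.48 from S. pombe probe sets (dashed line). THP3 lies above the limit in all 6 arrays, and the reporter probe set lies above it in the arrays labelled wild type alone.

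Among the 5449 genes the largest difference was that of PHO84, the high-affinity phosphate transporter, which was 73.4-fold higher in the arrays labelled deletion (log2 difference 6.20 ± 0.12, 3 arrays per group, adjusted p = 2.33e-06). In the arrays labelled wild type PHO84 stood at 6.77 ± 0.26 (SD), close to the background limit of 6.48, so the size of this fold is uncertain. SPL2, an inhibitor of low-affinity phosphate uptake, was at least 4.61-fold higher, since the other group lay below the background limit. The acid phosphatase gene PHO5 rose 4.18-fold. RPS22B, a gene of the small ribosomal subunit, rose 4.96-fold, and the flocculin-like BSC1 5.61-fold. FDC1 (a decarboxylase of phenylacrylic acids), the pheromone-regulated PRM7, the iron-reductase homologue FRE4 and the uncharacterized YNL040W rose between 3.06- and 4.15-fold. Of the 10 largest falls, 5 lay on chromosome X: SFC1 (mitochondrial succinate and fumarate transport), LSO1, PRM10, RSF2 and RRN7, with log2 differences between -1.70 and -1.26. The other 5 were the kinase homologue KDX1 (-1.68 ± 0.06), the small heat-shock gene HSP12 (-1.33 ± 0.07), YIR042C (-1.29 ± 0.14), YER053C-A (-1.27 ± 0.24) and BAG7 (-1.26 ± 0.07), a GTPase-activating protein gene of the cell wall pathway.

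In total 1184 of 5449 genes passed the threshold, 630 higher and 554 lower in the arrays labelled deletion. With the values as deposited the split was 479 higher and 635 lower. At least 2-fold changes were found for 78 genes, 20 higher and 58 lower. Outside chromosome X, 889 of 5133 genes passed, 630 higher and 259 lower, and 33 of them changed at least 2-fold. With the chromosome X genes left out before the fit, 761 genes passed (536 higher, 225 lower). Within the arrays numbered 1 and 2 the count was 822, and with the arrays numbered 3 as a batch it was 1573. The groups did not overlap for 2247 genes, where chance gives 10%.

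**Figure D2:**
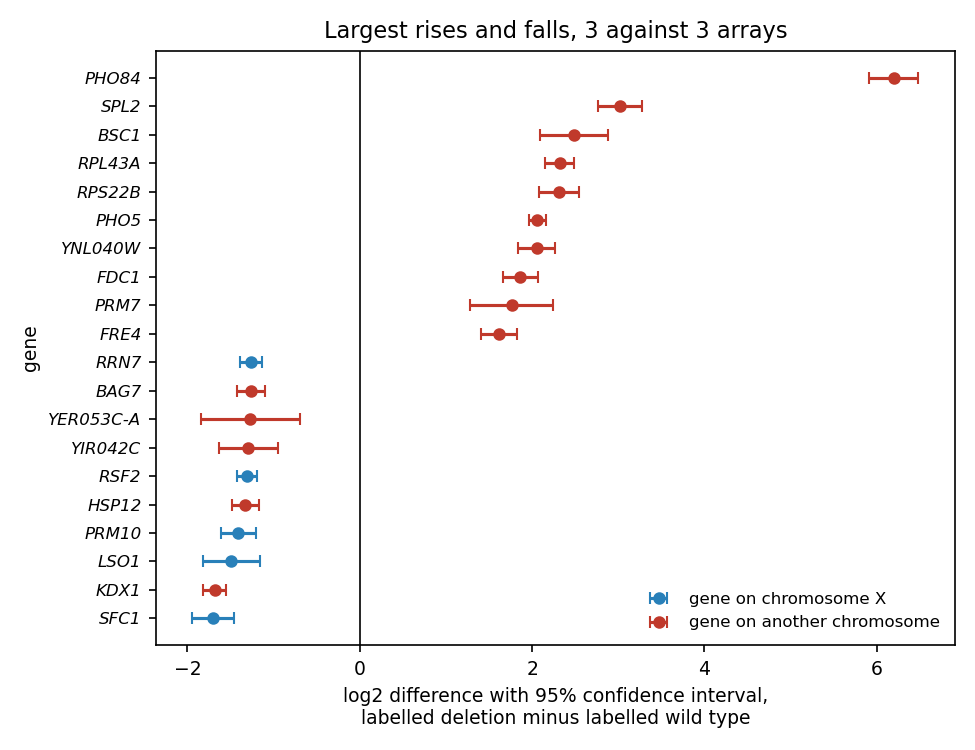
Log2 difference, arrays labelled deletion minus arrays labelled wild type, of the 10 largest rises and the 10 largest falls, with 95% confidence intervals from limma (3 against 3 arrays) and chromosome X genes in blue. PHO84 stands at 6.20, and 5 of the 10 falls are chromosome X genes.

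Genes of chromosome X were lower together in the arrays labelled deletion. Of its 316 measured genes 295 fell, 0 rose and 21 did not pass the threshold. Examples are the transporter gene SFC1, the cell cycle gene CDC6 (-1.21 ± 0.11), the histone chaperone gene ASF1 (-0.94 ± 0.05) and the proteasome gene PRE3 (-0.66 ± 0.04). The median log2 difference was -0.79 on chromosome X and between 0.03 and 0.07 on each of the other 15 chromosomes. Relative to the other chromosomes it was -0.83, a 1.78-fold difference. The median level of chromosome X genes minus that of all others was 0.79 ± 0.01 (SD, n = 3) in the arrays labelled wild type and -0.14 ± 0.01 in those labelled deletion (exact permutation p = 0.1, the smallest possible). For the other 15 chromosomes this value lay between -0.45 and 0.20 in the arrays labelled wild type. In those labelled deletion it lay between -0.40 and 0.34. Chromosome X thus lay outside the range of the others only in the arrays labelled wild type. In 14 windows of 20 consecutive genes and a last one of 36, from one end of the chromosome to the other, the medians lay between -0.88 and -0.69. Among the 21 genes not called were RPL43B, TDH1 and TIF2, with differences of -0.11, -0.08 and -0.07. These 3 were chosen after their values were seen, and each is known to have a closely similar relative elsewhere in the genome. They were also bright, at 14.24, 13.50 and 14.21 in the arrays labelled wild type, and the reason for their small differences was not tested. Others of the 21 were dim, such as HXT8 and SET4, which lay below the background limit in the arrays labelled deletion. SPC1 differed by -1.15 ± 0.33 and missed the threshold (limma adjusted p = 0.052). Camera called chromosome X (adjusted p = 9.15e-118) and, at a relative median of 0.04, chromosome V (adjusted p = 0.021). With an estimated correlation the adjusted p was 7.05e-05 for chromosome X and 0.43 for chromosome V.

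**Figure D3:**
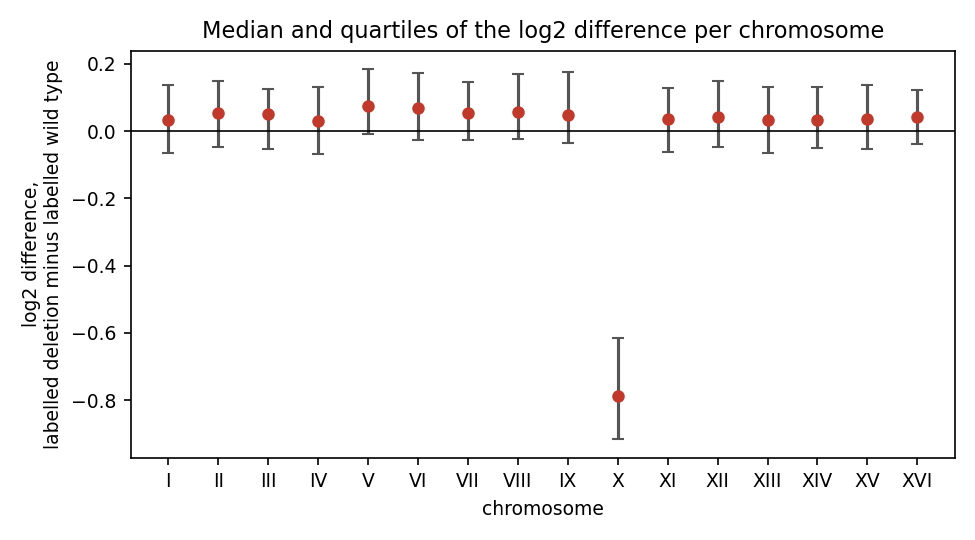
Median (points) and quartiles (bars) of the log2 difference, arrays labelled deletion minus arrays labelled wild type, over the genes of each of the 16 chromosomes. Chromosome X stands at -0.79 and the others between 0.03 and 0.07.

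Of the lists written beforehand, 3 were called upward. Of 17 measured phosphate genes 11 rose and 2 fell, PHO86 and VTC4, which lie on chromosome X. Adjusted over the list alone, 11 rose and 4 fell. Besides PHO84, SPL2 and PHO5, the polyphosphate synthesis gene VTC3 rose 2.47-fold (log2 difference 1.31 ± 0.04). Camera called the list upward (adjusted p = 0.0020; adjusted p = 0.28 with an estimated correlation). Genes of multidrug resistance rose in 9 of 16 cases and fell in 0, with 11 and 0 adjusted over the list alone. They included the transporters PDR15 (0.53 ± 0.06), TPO4 (0.58 ± 0.08), ATR1 (0.51 ± 0.08) and the sphingoid base exporter RSB1 (0.73 ± 0.09). The list was called upward (adjusted p = 0.0023; adjusted p = 0.58 with an estimated correlation). Genes of the mitochondrial ribosome rose in 12 of 66 cases and fell in 4, all 4 on chromosome X (MRPL8, RSM26, MRPL49 and RSM7), and the same counts were found adjusted over the list alone; with the values as deposited 7 rose and 4 fell. The largest rise among them, chosen after the values were seen, was RSM19 at 0.33 ± 0.06. Camera called this list upward too (adjusted p = 0.0067; adjusted p = 0.91 with an estimated correlation).

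Of 38 genes that peak at the start of the cell cycle 20 fell and 0 rose in the arrays labelled deletion, and 24 fell adjusted over the list alone. CDC6, SMC3, ASF1 and RFA3 lie on chromosome X, and the other 16 falls did not. Among those, chosen after their values were seen, were the cyclin genes CLN2 (-0.90 ± 0.11) and PCL1 (-0.52 ± 0.12) and the ribonucleotide reductase gene RNR1 (-0.47 ± 0.05). Camera gave an adjusted p of 6.72e-11 (adjusted p = 0.28 with an estimated correlation). Of 22 genes of G2 and mitosis 4 fell and 0 rose (4 and 1 adjusted over the list alone): BUD4 on chromosome X, DBF2, ALK1 and HST3. Their list was called downward (adjusted p = 0.035; adjusted p = 0.91 with an estimated correlation), but not without wild_type replicate 1 (adjusted p = 0.055), without wild_type replicate 2 (adjusted p = 0.084) or without ypr045c_deletion replicate 3 (adjusted p = 0.22). Nor was it called without both arrays numbered 3 (adjusted p = 0.076) or with quantile normalization over S. cerevisiae probe sets (adjusted p = 0.059); the range over all alternatives was 0.0054 to 0.91. Of 18 genes of the M/G1 transition and daughter cells 6 fell and 0 rose (6 and 1 adjusted over the list alone). They included PRY3, CDC6 and FAR1 on chromosome X and the cyclin-kinase inhibitor gene SIC1 (-0.32 ± 0.04). This list was called downward (adjusted p = 0.022; adjusted p = 0.58 with an estimated correlation), and without chromosome X genes it was not (adjusted p = 0.058; range over all alternatives 0.012 to 0.58).

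Members of subtelomeric gene families fell in 10 of 25 cases and rose in 0, with 13 and 0 adjusted over the list alone. AAD10 and DAN4 lie on chromosome X, while IMD2 (-0.85 ± 0.10), an enzyme of GTP synthesis, and VTH1 (-0.66 ± 0.08) do not. Both were read from probe sets of a type known to match more than 1 transcript, and VTH1 is known to have a close copy, VTH2, on chromosome X, so its fall may be that of VTH2. The list was called downward (adjusted p = 8.55e-06; adjusted p = 0.28 with an estimated correlation). Genes of the TCA and glyoxylate cycles and gluconeogenesis fell in 9 of 26 cases and rose in 1, with 11 and 1 adjusted over the list alone. The fructose bisphosphatase gene FBP1 fell 2.24-fold (-1.16 ± 0.05), the isocitrate dehydrogenase genes IDP2 and IDH2 by less (-0.39 ± 0.06 and -0.22 ± 0.04), and the citrate synthase gene CIT3 rose (0.47 ± 0.08). Camera called this list downward (adjusted p = 0.0081; adjusted p = 0.58 with an estimated correlation), but not when genes of several lists were counted in the smaller list alone (adjusted p = 0.059; range over all alternatives 6.63e-05 to 0.58). Of 37 proteasome genes 2 fell, PRE3 on chromosome X and RPT6 (-0.16 ± 0.04), and 0 rose; adjusted over the list alone 1 fell. This list was called downward (adjusted p = 0.035; adjusted p = 0.91 with an estimated correlation). It was not called with median centring (adjusted p = 0.090), without wild_type replicate 2 (adjusted p = 0.084), without ypr045c_deletion replicate 1 (adjusted p = 0.10) or with quantile normalization over S. cerevisiae probe sets (adjusted p = 0.077), with a range of 0.0015 to 0.91 over all alternatives. In all, 9 of 46 lists were called, 3 upward and 6 downward, and 0 with an estimated correlation.

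Complexes near the Thp3 protein were examined because Thp3 is linked to the coupling of transcription and mRNA processing. Of 23 genes of the THO and TREX-2 export complexes 2 rose in the arrays labelled deletion, MTR2 (0.29 ± 0.04) and CDC31 (0.25 ± 0.04), and 0 fell, over all genes and adjusted over the list alone. HRB1 and HPR1 differed by 0.13 and 0.14 and were not called. The list was not called (camera adjusted p = 0.55). Of 5 genes like those of the COP9 signalosome, RRI2 rose (0.30 ± 0.06), and the count was the same adjusted over the list alone (list adjusted p = 0.89). Of 27 transcription elongation genes 2 rose and 3 fell, CTK2, RPB4 and SET2, all on chromosome X. With the values as deposited 0 rose and 3 fell. Adjusted over the list alone 1 rose and 3 fell (list adjusted p = 0.65). Its median was 0.03, and -0.02 with the values as deposited; its mean was -0.06. Of 86 spliceosome genes 11 rose and 4 fell (9 and 8 with the values as deposited), among which ISY1, PRP21 and LSM8 lie on chromosome X, and adjusted over the list alone 9 rose and 4 fell. SNU23 rose (0.31 ± 0.04). The list was not called (adjusted p = 0.65).

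Intron-containing genes were compared because Thp3 is known to be linked to splicing; the arrays measure mRNA levels, not splicing. The 82 ribosomal protein genes with an intron had a median log2 difference of 0.01, the 45 without one 0.02, and the 126 other genes with an intron 0.06. In these classes 3, 2 and 14 genes rose and 5, 1 and 9 fell, and of those that fell 4, 1 and 5 lay on chromosome X. Camera called no class (adjusted p = 0.88, 0.59 and 0.59), and exact permutation tests of the class medians per array gave p = 0.4, 0.2 and 0.2 (n = 3 per group). The ribosomal protein list had the highest median level of the lists, 14.14 in both groups. How far these arrays understate differences at that level was not measured. Medians near 0 therefore do not show that ribosomal protein mRNA was unchanged. With median centring both ribosomal protein classes were called upward (adjusted p = 0.043 with an intron and 0.032 without), where the other alternatives run for these classes left them uncalled, with adjusted p up to 0.99 and 0.90. RPL43A and RPS22B were the largest rises of the ribosomal protein list, followed by RPL22B (0.59 ± 0.05), while RPS14B on chromosome X fell (-0.42 ± 0.07). Of the 128 measured genes of that list 5 rose and 6 fell (5 and 3 with median centring), and 4 and 4 adjusted over the list alone (camera adjusted p = 0.79; called upward with median centring, adjusted p = 0.027; range over all alternatives 0.027 to 0.99). The list of other intron-containing genes, 125 without ASC1, had 14 rises and 9 falls, against 7 and 10 with the values as deposited and 18 and 8 with median centring, and 13 and 8 adjusted over the list alone (adjusted p = 0.52). Its members with the smallest p, APS3, NSP1, BET4 and PRE3, all lie on chromosome X and fell.

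Gene length, introns included, was compared because mutants of the related THO complex express long genes poorly. Across the 5449 genes, which are not independent replicates, the log2 difference fell with gene length (Spearman rho = -0.19, and rho = -0.21 without chromosome X genes). The median level of the 25% longest genes (at least 1899 bp) minus that of the 25% shortest (up to 756 bp) was -0.11 ± 0.02 in the arrays labelled wild type and -0.19 ± 0.03 in those labelled deletion (SD, n = 3 each). The difference between the groups was -0.08, larger than the spread between arrays (exact permutation p = 0.1, the smallest possible).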

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

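The tests in this part were chosen after the results were seen. Probe sets outside the gene comparison differed between the labelled groups. The reporter probe set RPTR-Sc-AJ002682-1_s_at had signal in all 3 arrays labelled wild type and none above the background limit in the others. Its fitted log2 difference, labelled deletion minus labelled wild type, was -8.70, which is no measure of size; against the limit it was at least 197-fold. Reporter probe sets of the J01347 series were higher in the arrays labelled deletion: RPTR-Sc-J01347-1_at by 0.77, RPTR-Sc-J01347-1_s_at by 1.48, RPTR-Sc-J01347-2_at by 0.79, RPTR-Sc-J01347-3_at by 1.53 and RPTR-Sc-J01347-4_at by 0.80. RPTR-Sc-U46493-1_s_at was higher by 1.01. These 7 were the reporter probe sets, of 47, that passed the threshold (limma, adjusted over all probe sets). The tables used here do not say what they detect.

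Of the 166 control probe sets 2 passed, both for EAF5, with differences of 0.35 and 0.34; the gene's own probe set differed by 0.30 ± 0.06. Among the 3470 unnamed probe sets 81 passed, 32 higher and 49 lower in the arrays labelled deletion, and the largest difference each way was 1.04 and -2.09. Of the 1746 S. pombe probe sets 13 passed.

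In the arrays labelled deletion THP3 was not lower, and a probe set outside the deleted part may account for its signal there, 8.77-fold over the background limit. LEU2, deleted in BY4741, also stood above that limit in both groups, so a signal over it does not by itself show an intact gene. An exchange of the 2 groups' labels would put the deletion among the arrays labelled wild type, where THP3 stood 6.99-fold over the limit; if the reporter probe set bright in these arrays alone detects a marker inserted with a deletion, which no table used here says, its signal would go with this and with the next explanation. Another candidate explanation is a deletion of the neighbouring RPL43A in the strain labelled wild type: RPL43A was among the 10 largest rises, but its signal there was still 44.3-fold over the limit, which its paralog RPL43B on chromosome X may supply. Together with an extra copy of that chromosome, itself left open, this would cover its shift too. RPL43B differed by only -0.11, but this does not weigh against it if the RPL43B probe set also reads RPL43A. These explanations cannot be told apart, because no table used here gives probe positions or sequences, and a deletion of YPR045C as labelled stays open.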

How the results depend on the processing

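Of the alternatives, 4 were chosen after the data were seen: without chromosome X genes, without both arrays numbered 3, with those as a batch, and quantile normalization over S. cerevisiae probe sets. Of 191 values of the compared quantities, 181 kept direction and side of the threshold, or stayed within 1.5 times for counts or the spread between arrays for untested values. An unmoderated unequal-variance test called 558 genes. Without chromosome X genes 761 genes were called, 33 of them changed at least 2-fold. Only part of this loss is the chromosome X genes themselves, since the main fit called 889 genes outside that chromosome. All 761 were also called in the main fit. Without the many small p-values of chromosome X, the Benjamini-Hochberg method sets a stricter limit on p for the other genes. The spread was also estimated anew, and how much each contributed to the further loss was not tested. Camera with an estimated correlation called 0 lists and 1 chromosome, X. With median centring the ribosomal protein classes with and without an intron had medians of 0.0624 and 0.0681 and were called. THP3 was called higher in the arrays labelled deletion at 0.41 without both arrays numbered 3 and at 0.33 with them as a batch. It stood at 8.94 and 9.10 in those arrays and between 9.43 and 9.93 in the others. In the main fit this gap counts as spread within the groups. What set those arrays apart was not tested.

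With the array number as a replicate block, 1297 genes were called, and THP3 was called at 0.33 (adjusted p = 0.025); of the other compared quantities 0 changed, while UMP1, MCM16 and the stress-induced and ribosome biogenesis lists gained a call. Deviations of same-numbered arrays correlated at -0.15, -0.03 and 0.61, so the numbers do not pair the arrays. Number 3 correlated best with its own number, while numbers 1 and 2 correlated best with each other, at 0.48 and 0.47.

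Leaving out 1 array at a time gave 830 to 983 genes changed, 72 to 82 changed at least 2-fold and 7 to 11 lists; the THP3 difference ranged from 0.15 to 0.58 and that of chromosome X from -0.83 to -0.82. Of 1184 genes called, 974 were also called with the values as deposited and 760 without both arrays numbered 3. With 1 array left out, 68.6% to 77.0% of them were also called. Named genes, apart from the neighbours of THP3, were chosen from these data for large differences or small p, which favours keeping their calls. Among named genes, 1989 of 2067 values kept direction and call, 60 lost the call, 11 gained one and 7 changed sign, all 7 not called in either setting. The latter were RRI1 at 0.0119 as deposited, 0.0588 with median centring, 0.00181 without wild_type replicate 3 and 0.00830 without ypr045c_deletion replicate 1 (range with 1 array left out from -0.0820), CSI1 at 0.0231 with median centring, and MET17 at -0.00759 and MF(ALPHA)1 at -0.0647 with normalization over S. cerevisiae probe sets. Of the called lists, 9 were lost with an estimated correlation, and 11 of the other values lost the call. Signal over background limits the dim genes: URA3 and MET17 lay below the background limit in both groups.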

Other observations

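Several other lists had members on both sides of the comparison, with directions by the labels. Of 30 iron-response genes 14 rose in the arrays labelled deletion and 6 fell (15 and 7 adjusted over the list alone). The reductase gene FRE4 (1.61 ± 0.09) and the siderophore transporter ENB1 (0.70 ± 0.05) rose, while FRE5 (-0.64 ± 0.06) and BNA2, on chromosome X, fell. The list was not called by camera (adjusted p = 0.36). Of 32 haploid-specific and pheromone-response genes 5 rose and 7 fell (9 and 7 adjusted over the list alone; camera adjusted p = 0.82). The agglutinin gene AGA1 (1.49 ± 0.09) and the fusion gene FUS1 (0.94 ± 0.07) rose, and PRM10 and STE18 on chromosome X fell. Of 7 genes specific to a cells, MFA1 rose (0.50 ± 0.05) and ASG7 on chromosome X fell; AGA2 and BAR1 differed by 0.15 and -0.10. Adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.95). Of 4 alpha-specific genes SAG1, on chromosome X, fell by 1.23 and STE3 rose by 0.45 (adjusted p = 0.048). The call of STE3 was lost in most alternatives; over all of them its adjusted p ranged from 0.027 to 0.18. Of 5 auxotrophic marker genes 0 were called, also adjusted over the list alone; URA3 and MET17, both deleted in BY4741, lay below the background limit in both groups. LEU2, also deleted there, stood above it at 8.79 and 8.52, and LYS2, intact in BY4741, stood at 12.00 and 12.09.

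Of 53 meiosis and sporulation genes 10 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.18; range over all alternatives 0.0069 to 0.95). It was called upward with the values as deposited, with median centring and without ypr045c_deletion replicate 1 (adjusted p = 0.041). HOP1 rose at least 1.48-fold against the background limit and SPO22 by 0.77 ± 0.05, and IME2 and REC107 on chromosome X fell. Genes under nitrogen catabolite control rose in 10 of 30 cases and fell in 3 (10 and 5 adjusted over the list alone; camera adjusted p = 0.36), with the proline oxidase gene PUT1 at 1.00 ± 0.09 and the arginine permease gene CAN1 at 0.38 ± 0.04. Of 67 stress-induced genes 9 rose, among them DDR48 (0.91 ± 0.05), and 16 fell, among them HSP12, the aldehyde dehydrogenase gene ALD4 (-1.13 ± 0.06) and the stress regulator gene MSN4 (-0.95 ± 0.09). Adjusted over that list alone 9 rose and 18 fell (camera adjusted p = 0.074; range over all alternatives 0.0012 to 0.91). It was called downward in 5 of 20 alternatives, among them without chromosome X genes (adjusted p = 0.0012), without wild_type replicate 3 (0.042) and without ypr045c_deletion replicate 2 (0.011). Of 37 cell wall integrity genes 4 rose and 11 fell (1 and 10 with the values as deposited), including KDX1, BAG7 and the mannoprotein gene CWP1 (1.99-fold); adjusted over the list alone 6 rose and 12 fell (camera adjusted p = 0.074; range over all alternatives 0.010 to 0.91). This list was called downward without chromosome X genes (adjusted p = 0.010), without ypr045c_deletion replicate 3 (0.041) and without both arrays numbered 3 (0.034). In amino acid biosynthesis 12 of 57 genes rose, ARG1 most (1.57 ± 0.07), and 8 fell, among them LEU1 (-0.49 ± 0.04); adjusted over the list alone 14 rose and 9 fell (camera adjusted p = 0.55).

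In what follows, the tests of chromosome X and of the phosphate genes were chosen after the results were seen; the counts over other splits were not. Chromosome X genes differed by -0.83 relative to the others. The between-array normalization applied here is argued against as the cause by -0.84 with the values as deposited, and a single region or few genes by a highest window median of -0.69. How the authors scaled the deposited values is not given, so their scaling was not tested as a cause. One extra copy of chromosome X in the strain labelled wild type may account for the shift. In a haploid it predicts -1, which no window reached, nor did any of 3 classes of genes by mean level (-0.89, -0.93 and -0.75 from dim to bright). The classes were taken relative to the other chromosomes. The windows were not, and the median of the other chromosomes was 0.04. By its level, chromosome X stood apart from the others in the arrays labelled wild type (0.79) and not in those labelled deletion (-0.14). This goes with a raised chromosome X in the former rather than a lowered one in the latter. How far these arrays understate a 2-fold difference was not measured, nor was DNA. An extra copy therefore stays open, and an effect of the deletion on this chromosome stays untested.

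Of 17 phosphate genes 11 were higher in the arrays labelled deletion, PHO84 most. The list's median was 0.36 with all arrays and 0.32 without both arrays numbered 3, but each group holds 1 of these, so this comparison tests no batch as the cause of a group difference. A later growth stage of the cultures labelled deletion could raise these genes, and the stress-induced list, with a median of -0.0484, called downward in some alternatives, does not settle it because its members went both ways. The TCA and glyoxylate list went against it, with a median of -0.09, 9 falls and 1 rise, but was not called with an estimated correlation (adjusted p = 0.58; range 6.63e-05 to 0.58). A difference in phosphate between the cultures, if there was one, cannot be told apart from the labels, and an effect of the deletion stays open as well.

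Of the 10 splits of the 6 arrays into 3 and 3, only the labelled one gave as many as 1184 changed genes (1 split; highest of the others 0) or 78 changed at least 2-fold (1 split; highest of the others 0). For the gene lists 2 splits gave as many as the 9 called, with 10 in the split that set wild_type 1, wild_type 3 and ypr045c_deletion 1 against the rest, which does not follow the array numbers. For chromosomes the labelled split gave 2, X and V, and each of the others gave 1. Chromosome V was not called with an estimated correlation (camera adjusted p = 0.43). This count therefore hardly sets the labelled split apart. Every other split puts arrays of both labels in each group. The difference between the labels then enters its spread and lowers its count of changed genes. The counts of 0 are therefore no measure of chance. With 10 splits the share cannot fall under 0.1.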
